A study of Homo sapiens with 3 samples.

How the data were processed

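Poly(A) RNA of Jurkat cells was measured in 3 libraries, 1 each of PBIT at 10 µM for 5 h, PBIT at 10 µM for 24 h and DMSO, which the labels place at 5 h. The libraries were made with a TruSeq RNA kit that does not mark strand and were sequenced in pairs of reads on a NextSeq 500, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19.0, STAR 2.7, Subread and featureCounts 2.0.0, and the build hg19. The authors deposited 1 table of raw counts per gene, with a column for each library beside the position, strand and length of each gene, per the file headers. The strand setting, the treatment of reads with several matches, the annotation release and whether reads or pairs were counted are not given in the sources used here. Among genes with 1 to 199 counts, 60.9% of counts in the DMSO library, 59.4% in the PBIT 5 h library and 60.8% in the PBIT 24 h library were even, an excess over an equal split of even and odd counts. If mates of a pair were counted separately the counting intervals are too narrow, so counts halved and rounded down were tried as an alternative.

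The table holds 20356 Ensembl gene IDs, of which 19446 matched a symbol in a table of gene names and 910 did not. It includes 13 genes of the mitochondrial genome. Coordinates are given as in the table, from the first exon start to the last exon end, 1-based on hg19. The reference at hand was of another build, so its coordinates were not used, and its GENCODE 29 transcripts served only for the median GC content of each gene's coding transcripts, found for 13863 of the 14463 tested genes (95.9%). Exons that overlap those of another gene in the table, on either strand, were recorded, since the counts of such genes, and of near-identical copies, are uncertain. Among the genes described, such overlaps were found for OSGIN1, ATP6V0A4, KDM5A, HSP90B1, DNAJB11, ATF5, PFKFB4, CRYAB, HSPA1A, DAAM2, NDUFA1, PSMA6, KRT8, RAD54L, HLA-DPB1 and EPOR.

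Total deposited counts were 109759169 for DMSO, 115900579 for PBIT 5 h and 100840312 for PBIT 24 h. Mitochondrial genes took 2.31%, 2.72% and 2.10% of the counts in that order, and the 10 most abundant genes took 5.31%, 5.45% and 4.62%. Genes with at least 20 counts in at least 1 library were kept, which left 14463. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), and log2 CPM were computed with a prior count of 2, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, by a formula checked against edgeR. For each pair of libraries the log2 ratio of CPM was taken with the exact (Clopper-Pearson) 95% binomial interval of the ratio of counts. These intervals cover counting error only, not the spread between cultures, and sequenced PCR copies are not independent molecules. With 1 library per group no p-value, standard error or standard deviation between replicates could be had. The median width of the interval was 0.14 on the log2 scale at 5 h against DMSO and 0.15 at 24 h. The size rule used the ratio with the prior count for every gene, while a fold printed against a count of 0 is a bound with a floor of 3 counts per library. By total counts, without TMM scaling, this floor is 0.0273 CPM in DMSO, 0.0259 at 5 h and 0.0298 at 24 h. Of the genes past the size rule, 0 at 5 h against DMSO, 14 at 24 h against DMSO and 16 at 24 h against 5 h had a count of 0 in a compared library, and with the floor in the size rule 0, 13 and 16 of such genes were past it.

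The comparisons were PBIT 5 h against DMSO, PBIT 24 h against DMSO and PBIT 24 h against PBIT 5 h. A gene passed the size rule when its ratio was at least 2-fold either way and its interval excluded no change. The comparisons, the size rule, most of the other settings tried, 37 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 members among the tested genes, 34 of them, were described by the median log2 ratio and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart when its median lay outside the middle 95% of these random lists, as a description of these libraries. Named genes were, for each PBIT library against DMSO, the 10 higher and 10 lower genes past the size rule whose interval bound nearest to no change was farthest from it, leaving out clone-based names, small RNAs, pseudogenes and mitochondrial genes, up to 4 members of each list, those past the rule first and then by the same bound, and the KDM5 genes. Pseudogenes were taken from RefSeq biotypes. For PBIT 24 h against PBIT 5 h and for genes shared by both times the rule named 5 per direction. Some genes that these rules name are not reported here. The KDM5 genes described were KDM5A, KDM5B and KDM5C, without KDM5D of the Y chromosome.

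Because both PBIT libraries were compared with the same DMSO library, 100 sets of 3 unchanged libraries were simulated as Poisson counts from the pooled profile at the real totals, with counting error and no spread between cultures. The procedure was tested on simulated Poisson counts, also without spread between cultures, for PBIT 5 h against DMSO. In these data 14328 genes were past the filter and 200 genes were changed. The size rule called 100.0% of genes changed 4-fold in either direction, 94.1% of those raised 2.5-fold and 97.0% of those lowered to 0.4 of their level. It called 2.9% of genes raised 1.5-fold, 0.0% of those lowered to 0.667 of their level and 0.08% of unchanged genes. These rates hold for counting error only, and the few calls at 1.5-fold follow from the 2-fold limit. Of 100 lists of 30 genes drawn at random from the simulated libraries, 8 fell outside the middle 95% of 1000 matched random lists, where 5 would by chance.

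Other settings fixed before the data were seen were DESeq2 1.42.0 size factors, scaling by total counts, no filter (1 count in 1 library), a filter of 100 counts, a prior count of 0.5, thresholds of 1.5-fold and 4-fold, the whole interval beyond 2-fold, thinning to the smallest library, leaving out mitochondrial genes, and 5 expression bins. Halved counts, removal of lowess trends (span 0.3) on GC and then on gene length, random lists matched on GC as well as expression (10 bins of each), and the floor of 3 counts in the size rule were added after the data were seen.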

Results

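Poly(A) RNA of Jurkat cells, an established line of human T-cell acute lymphoblastic leukaemia, was sequenced after culture with PBIT or with its solvent DMSO. PBIT is a small molecule known as an inhibitor of the KDM5 (JARID1) enzymes, which remove methyl groups from lysine 4 of histone H3, a mark of active promoters. The 3 libraries were 1 of cells kept with 10 µM PBIT for 5 h, 1 of cells kept with 10 µM PBIT for 24 h, and 1 of DMSO-treated cells, which carries a time of 5 h. The deposited gene counts summed to 109759169 in the DMSO library, 115900579 in the PBIT 5 h library and 100840312 in the PBIT 24 h library. There were no replicates, so no test of the conditions was possible. Each difference below is between 2 libraries and is given as a log2 ratio of CPM, the counts scaled to a common library size by TMM. The ratio includes a prior count of 2, which pulls ratios of low counts towards no change. The 95% interval in parentheses is that of the counts without the prior count, and it covers counting error only. A gene was past the size rule when its ratio was at least 2-fold in either direction and its interval excluded no change. Gene coordinates are those of the deposited table, on hg19.

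The mRNAs of KDM5A, KDM5B and KDM5C, of the demethylase family that PBIT is known to inhibit, were at similar levels in the 3 libraries. KDM5A (ENSG00000073614, chromosome 12, 389295 to 498620) had 121 CPM in DMSO, 122 at 5 h and 111 at 24 h of PBIT. KDM5B (ENSG00000117139, chromosome 1, 202696526 to 202778598) had 79.5, 81.3 and 81.7 CPM, and KDM5C (ENSG00000126012, chromosome X, 53220503 to 53254604) had 109, 114 and 125 CPM. None of these 3 genes was past the size rule at 5 h or 24 h. The log2 ratio to DMSO farthest from 0 among them was that of KDM5C at 24 h, 0.20 (0.17 to 0.24). Exons of KDM5A overlap those of CCDC77, so reads of the shared stretch cannot be assigned to either gene with certainty.

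The first comparison, PBIT 5 h against DMSO, addressed the early response at matched hours. Genes of the antioxidant response that the transcription factor NRF2 controls were higher in the PBIT library. HMOX1 (haem oxygenase; ENSG00000100292, chromosome 22, 35776354 to 35790207) was 2.87-fold higher, with 685 against 220 counts and a log2 ratio of 1.52 (1.31 to 1.76). OSGIN1, an oxidative stress-induced growth inhibitor, stood at 1.37 (1.27 to 1.46), and the quinone reductase NQO1 at 1.07 (1.01 to 1.13). The mRNA of thioredoxin reductase, TXNRD1, reached 1267 CPM against 751, a log2 ratio of 0.76 (0.74 to 0.77) that lay under the 2-fold limit. Of the 20 measured members of the NRF2 list, 3 were past the size rule as higher, 0 as lower and 17 as neither. All 20 had log2 ratios above 0 with TMM scaling, and 19 did with DESeq2 size factors. The list median was 0.45, above the random lists matched on expression, whose middle 95% spanned -0.09 to 0.02.

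Across all 14463 genes past the count filter, 117 were higher and 39 lower at 5 h by the size rule. Among genes with a mean of at least 1 CPM in the compared libraries, 13 were higher and 0 lower. CRIM1 (ENSG00000150938, chromosome 2, 36583069 to 36778278), a transmembrane protein that binds bone morphogenetic proteins, had 6930 counts against 2096 and a log2 ratio of 1.62 (1.55 to 1.69). ATP6V0A4, a subunit of the vacuolar proton pump, had 311 counts against 94 (1.60; 1.28 to 1.97), and MEGF11, an EGF-domain membrane protein, had 123 against 27 (log2 interval 1.47 to 2.74). HMOX1 and OSGIN1, with 220 and 1310 DMSO counts, were also among the 10 named higher genes, and the remaining 5 had at most 6 DMSO counts each. The glutathione peroxidase GPX2 had 28 counts against 2 (2.81; 1.71 to 6.81), the transcription factor NFE2 20 against 1 (2.78; 1.57 to 9.59), and AMZ1 30 against 2 (2.90; 1.82 to 6.91). SIGLEC15 had 51 counts against 5, and the cytokine gene IL22 39 against 6. The 10 named lower genes, led by NPNT (2 against 20 counts), KANK4 (2 against 16) and the histone gene H2BC13 (6 against 26), had at most 70 counts in DMSO, the number for CMTM2.

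Several other groups stood apart from random lists at 5 h. Genes of NF-kB signalling were higher, with a list median of 0.31 (middle 95% of random lists -0.05 to 0.11) and 15 of 16 members above 0, although 0 were past the size rule as higher and 0 as lower. BCL3 stood at 0.97 (0.66 to 1.30), RELB at 0.57 (0.43 to 0.71), the inhibitor NFKBIA at 0.56 (0.47 to 0.64) and TNFAIP3 at 0.52 (0.47 to 0.57). The immediate early and activation list had a median of 0.18 (middle 95% of random lists -0.04 to 0.10), with 1 of 30 members higher by the rule, 0 lower and 29 neither. FOSL1 was the higher member at 1.06 (0.60 to 1.59), and DUSP4, JUN and the activation marker CD69 stood at 0.62, 0.49 and 0.45. Transcripts of the mitochondrial genome had a median of 0.16 (middle 95% of random lists -0.13 to 0.00), all 13 above 0 and none past the rule, with MT-ND2 at 0.32 (0.31 to 0.33) and MT-CO1 at 0.26 (0.25 to 0.26). The autophagy and lysosome list had a median of 0.05 (percentile 98.9) with none of 22 past the rule, TFE3 at 0.61 and GABARAPL1 at 0.37. After removal of the GC and length trends its percentile was 96.97, within the limits.

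Groups with lower medians at 5 h were the endoplasmic reticulum stress list and genes of growth and energy metabolism. The endoplasmic reticulum stress list had a median of -0.34 (percentile 0.0), with 18 of 21 members below 0 and none past the size rule. HSP90B1, the chaperone GRP94, stood at -0.64 (-0.65 to -0.64), the calcium-binding chaperone CALR at -0.55 (-0.56 to -0.54), the disulfide isomerase PDIA4 at -0.50 (-0.51 to -0.48) and MANF at -0.47 (-0.49 to -0.44). In the list of MYC targets and ribosome biogenesis, 30 of 30 members were below 0, none past the rule, and the median was -0.20 (percentile 0.0). MYC itself stood at -0.34 (-0.35 to -0.32), and the nucleolar proteins NCL and NPM1 at -0.32 and -0.31. The nuclear genes of oxidative phosphorylation had a median of -0.11 (percentile 0.01), with NDUFA1 at -0.21 and UQCRC2 at -0.18. Of its 40 members none was past the rule and 40 were below 0, against 37 with scaling by total counts. Medians of random lists matched on expression were mostly below 0 too, with limits of -0.0752 and -0.0019 for this list. For MYC targets the limits were -0.0905 and -0.0067. The numbers of members below 0 therefore do not by themselves set these lists apart. Ribosomal protein genes had 64 of 72 members below 0 at percentile 29.2, within the limits. The proteasome list had a median of -0.0975 (percentile 1.43), close to the limit of -0.0928. None of its 30 members was past the rule, and PSMA6 stood at -0.20. After removal of the GC and length trends its percentile was 9.57, within the limits.

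Lists of cytotoxic, epithelial and fibroblast markers were part of the same comparison. The list of natural killer and cytotoxic markers had a median of 0.31 (percentile 97.6), with 2 of 8 members higher by the rule, 0 lower and 6 neither. The protease gene GZMB had 297 counts against 123 (1.15; 0.86 to 1.48) and GNLY 26 against 10 (1.12; 0.17 to 2.49). The epithelial and fibroblast list had a median of 0.23 (percentile 98.3), none of 5 members past the rule, with VIM, which T cells also express, at 0.40 and KRT8 at 0.23. With 5 expression bins for matching, the percentiles of these lists were 95.1 and 97.26, within the limits. In all, 11 of 34 tested lists stood apart at 5 h, 7 higher and 4 lower, where 1.7 lists of randomly drawn genes would. Genes of a list can vary together between cultures, which 1 library per condition cannot show. The 1.7 is therefore no measure of chance between cultures. The number of genes past the size rule depended on low counts, since requiring at least 100 counts in at least 1 library left 19 higher and 0 lower. Halving all counts, tried because even counts were more frequent than odd ones, left 70 higher and 18 lower.

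**Figure D1:**
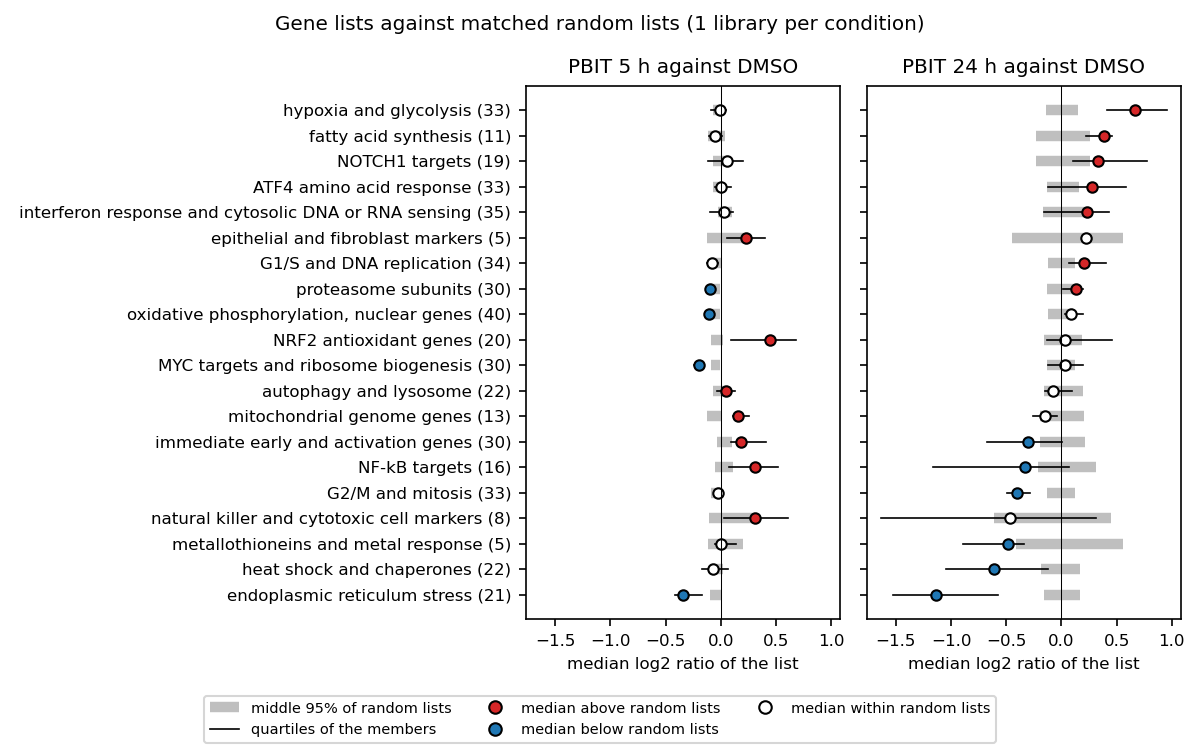
Median log2 ratio of each gene list that stood apart in at least 1 of the comparisons with DMSO, at 5 h on the left and at 24 h on the right, with the number of measured members in parentheses. Grey bars span the middle 95% of random lists matched on expression, thin lines span the quartiles of the members, and filled points lie outside the grey bars, such as the endoplasmic reticulum list at -0.34 and -1.13.

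The second comparison was PBIT 24 h against DMSO. The DMSO library carries 5 h, so PBIT and the longer culture cannot be told apart in any of the 24 h differences that follow. The largest coordinated difference by list median was lower expression of the endoplasmic reticulum stress list. HSPA5 (the chaperone BiP; ENSG00000044574, chromosome 9, 127997132 to 128003609) had 729.7 CPM against 3778, 5.18-fold lower, with a log2 ratio of -2.37 (-2.38 to -2.36). The co-chaperone DNAJC3 stood at -1.95 (-1.99 to -1.90), HSP90B1 at -1.90 (-1.91 to -1.89) and DNAJB11 at -1.59 (-1.62 to -1.56). Of the 21 list members, 12 were lower by the size rule, 0 higher and 9 neither, and the median was -1.13 (percentile 0.0; middle 95% of random lists -0.15 to 0.17). The heat shock and chaperone list was lower too, at a median of -0.61 (percentile 0.0), with 7 of 22 members lower by the rule, 0 higher and 15 neither. HSPH1 stood at -1.09 (-1.10 to -1.07). CRYAB had 3 counts against 79 (-3.94; -6.91 to -3.00). HSPA1A (-1.51) and HSPA1B (-1.26) are near-identical copies, so the split of reads between them is uncertain.

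Genes of hypoxia and glycolysis were higher in the 24 h library. Adrenomedullin, ADM (ENSG00000148926, chromosome 11, 10326227 to 10328944), had 190 counts against 22, a log2 ratio of 3.12 (2.59 to 3.94). The glycolytic regulator PFKFB4 stood at 1.52 (1.42 to 1.62), the mitophagy receptor BNIP3 at 1.42 and the growth factor VEGFA at 1.27 (1.18 to 1.38). Of 33 members, 8 were higher by the size rule, 0 lower and 25 neither, 32 were above 0, and the median was 0.66 (middle 95% of random lists -0.14 to 0.15). The fatty acid synthesis list had a median of 0.39 (percentile 99.8), with 1 of 11 members higher by the rule and 0 lower. That member was the fatty acid synthase FASN at 1.21 (1.18 to 1.23), beside SCD at 0.49 and ACLY at 0.42.

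**Figure D2:**
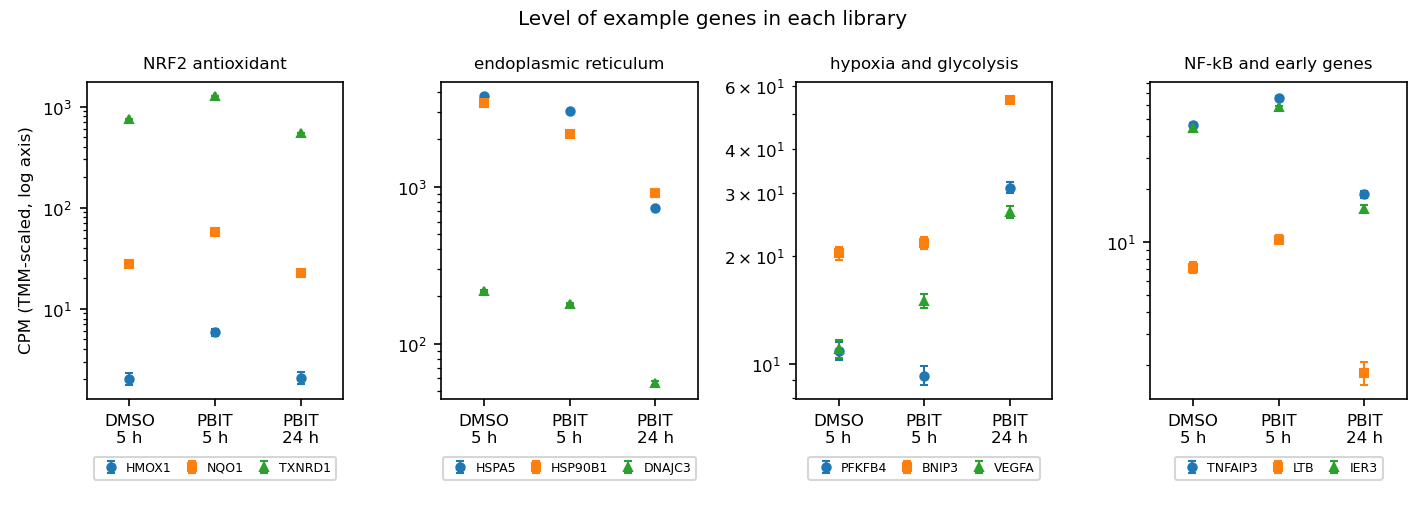
CPM of example genes in the 3 libraries on log axes that differ between panels, with bars for the 95% Poisson counting interval of each value. HSPA5 stood at 3778 CPM in DMSO, 3059 at 5 h and 729.7 at 24 h of PBIT, while HMOX1 stood at 2.02, 5.83 and 2.08.

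The cell-cycle lists went in opposite directions at 24 h. Genes of G2/M and mitosis had a median of -0.41 (percentile 0.0), 31 of 33 members were below 0, and none was past the size rule in either direction. UBE2C stood at -0.90 (-0.94 to -0.86), TOP2A at -0.69 (-0.70 to -0.68) and the proliferation marker MKI67 at -0.55. Genes of G1/S and DNA replication had a median of 0.20 (percentile 99.8), with 27 of 34 above 0 and none past the rule. The replication factor CDC45 stood at 0.83 (0.78 to 0.88) and the helicase subunit MCM6 at 0.59.

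Targets of NOTCH1, a receptor often mutated in this leukaemia, had a median of 0.33 at 24 h (percentile 99.4), with 3 of 19 members higher by the rule, 0 lower and 16 neither. CR2 stood at 1.86 (1.63 to 2.11), NOTCH3 at 1.53 (1.44 to 1.62), IGF1R at 1.03 (0.96 to 1.11) and DTX1, under the 2-fold limit, at 0.98. Against random lists matched on GC as well as expression, the percentile of this list was 97.35, within the limits. The interferon list had a median of 0.23 (percentile 97.9), with 2 of 35 members higher by the rule, OAS3 (1.37) and OAS2 (1.07), and 0 lower. The proteasome list had a median of 0.13 (percentile 98.2; 97.32 after removal of the GC and length trends), with none of 30 members past the rule and PSMD7 at 0.35. The ATF4 amino acid response list had a median of 0.28 (percentile 99.9), and its members went both ways, 5 higher, 3 lower and 25 neither by the rule. Among them STC2 stood at 1.67 and CHAC1, a glutathione-degrading enzyme, at 1.51, while the transcription factor ATF5 stood at -1.90 and asparagine synthetase, ASNS, at -1.67.

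Inflammatory and activation genes were lower at 24 h. The NF-kB list had a median of -0.33 (percentile 0.16), with 5 of 16 members lower by the rule, 0 higher and 11 neither. The lymphotoxin genes LTB and LTA stood at -1.98 (-2.23 to -1.76) and -1.63 (-1.78 to -1.49), BCL3 at -1.39 and TNFAIP3 at -1.30. The immediate early and activation list had a median of -0.30 (percentile 0.09), with 6 of 30 lower by the rule, 1 higher and 23 neither. NR4A3 stood at -1.92, IER3 at -1.51 and JUN at -1.25, while ATF3 was the higher member at 1.22. The metallothionein and metal response list, of 5 measured members, had a median of -0.49 (percentile 1.22), none past the rule, with MT1F at -0.95 and the zinc exporter SLC30A1 at -0.89. Among cytotoxic markers, GZMA (-1.64), PRF1 (-1.64) and GZMB (-2.15) were lower and the T-cell coreceptor gene CD8A (1.02) higher by the rule, and the list median of -0.47 lay at percentile 6.94, within the limits, and at 0.11 when at least 100 counts were required. The NRF2 list, at a median of 0.04 (percentile 65.2), did not stand apart at 24 h and had none of 20 members past the rule, with HMOX1 at 0.04 and TXNRD1 at -0.46.

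Of the 14463 genes, 410 were higher and 658 lower at 24 h by the size rule (316 and 242 among genes with a mean of at least 1 CPM). At 24 h 13 of 34 lists stood apart, 7 higher and 6 lower, where 1.7 lists of randomly drawn genes would. As at 5 h, this is no measure of chance between cultures. ASS1, argininosuccinate synthase of arginine synthesis (ENSG00000130707, chromosome 9, 133320316 to 133376661), had 46.8 CPM against 352, 7.52-fold lower (-2.91; -2.95 to -2.87). The collagen gene COL6A3 had 22 counts against 434 (-4.07; -4.87 to -3.56), and the calcium-binding protein gene CALB2 52 against 592 (-3.34; -3.83 to -2.98). KRT3, DMBT1, MYH15, B3GALT5 and ATP6V0A4 were also among the named lower genes, as was CRYAB, at log2 ratios from -4.47 for KRT3 to -3.29 for B3GALT5. Among the named higher genes, HES7 stood at 2.81 (2.31 to 3.54), the WNT ligand gene WNT8B at 238 against 38 counts, the endocytic receptor gene LRP2 at 1.93 (1.79 to 2.09), the proteoglycan gene VCAN at 2.12 (1.74 to 2.60) and IGLL1, a part of the pre-B cell receptor, at 1.92 (1.67 to 2.21). RHOBTB1 and NUDT8 stood at 1.83 and 1.75, and TSPAN1 and KISS1R had 32 and 71 counts against 3 and 12. Because the DMSO library carries 5 h, PBIT and the longer culture cannot be told apart in this comparison, and requiring at least 100 counts left 316 higher and 332 lower genes.

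The third comparison, PBIT 24 h against PBIT 5 h, was between the treated cells at the 2 times. Hours of PBIT and hours in culture cannot be told apart in it either. Genes lower at 24 h included ATP6V0A4 (4 against 311 counts; -5.52), KRT3 (-5.23), B3GALT5 (-4.32), DMBT1 (-4.27) and COL6A3 (-4.25). Genes higher at 24 h included WNT8B at 2.67 (2.25 to 3.24), the peptide hormone gene APLN at 2.09 (1.93 to 2.26), the WNT signalling gene DAAM2 at 1.98 (1.92 to 2.04), RPRML at 2.40 and KANK4, with 26 against 2 counts (2.97; 1.93 to 7.05). By the size rule 357 of 14463 genes were higher and 823 lower, against 282 and 335 among genes with a mean of at least 1 CPM and 274 and 438 when at least 100 counts were required. The NRF2 list was lower at 24 h than at 5 h, with a median of -0.27 (percentile 0.06), 4 of 20 members lower by the rule and 0 higher, and TXNRD1 at -1.21 (-1.22 to -1.20). The NF-kB list was lower at -0.80 (percentile 0.0; 6 of 16 lower, 0 higher), and the MYC and ribosome biogenesis list was higher at 0.23 (percentile 99.5), with 26 of 30 members above 0 (24 with scaling by total counts), none past the rule and MYC at 0.92. In all, 16 of 34 lists stood apart, 8 in each direction. The other higher ones were hypoxia and glycolysis (0.73), fatty acid synthesis (0.44), G1/S (0.28), NOTCH1 targets (0.27), nuclear genes of oxidative phosphorylation (0.27), ATF4 (0.26) and proteasome (0.22). Members past the rule went both ways among NOTCH1 targets (3 higher, 2 lower) and in the ATF4 list (4 higher, 3 lower). The other lower ones were endoplasmic reticulum stress (-0.74), heat shock (-0.50), immediate early genes (-0.49), G2/M (-0.34), mitochondrial genome genes (-0.32) and T cell identity (-0.17). The NOTCH1 percentile of 98.4 moved to 97.02 and the T cell identity percentile of 1.91 to 2.93, both within the limits, after removal of the GC and length trends.

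**Figure D3:**
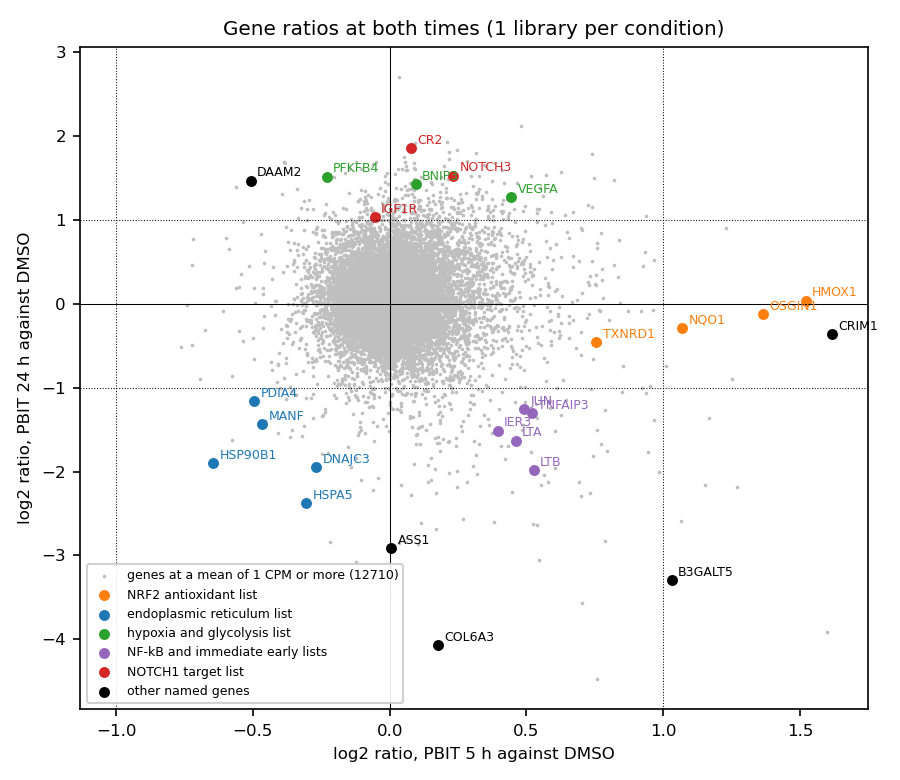
Log2 ratio to DMSO of each gene with a mean of at least 1 CPM over the 3 libraries, at 5 h of PBIT on the x axis and at 24 h on the y axis, with dotted lines at 2-fold and example genes coloured by list. HMOX1 lies at 1.52 on the x axis and 0.04 on the y axis, and HSPA5 at -0.30 and -2.37.

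Some genes were past the size rule at both 5 h and 24 h of PBIT. Of the 117 genes higher at 5 h, 17 were also higher at 24 h, and of the 39 lower at 5 h, 15 were also lower at 24 h, while 11 were higher at 5 h and lower at 24 h (10 with the floor of 3 counts in place of a 0), and 0 were lower and then higher. Independent lists of these sizes would share 3.32, 1.77, 5.32 and 1.11 genes in the same order, and simulated unchanged libraries that share their control gave means of 1.48, 0.52, 0 and 0. These simulations hold counting error only and no spread between cultures, so they are no measure of chance overlap between separate cultures. Their sets were also far smaller, with means of 6.65 higher genes at 5 h and 7.12 at 24 h, and 6.75 and 8.95 lower ones. The numbers of shared genes are therefore not comparable in size. The genes higher at both times rested on few DMSO counts, such as NFE2 (1 in DMSO, 20 at 5 h and 18 at 24 h), GPX2 (2, 28 and 15), SIGLEC15 (5, 51 and 22), the protease gene CAPN2 (9, 42 and 32) and the homeobox gene HOXB8 (16, 49 and 52). Those lower at both times included FOXD4 (70, 36 and 10 counts), GALNT15 (42, 19 and 6), CMTM2 (70, 35 and 25), MEIG1 (25, 9 and 5) and FNDC11 (20, 6 and 2). Across genes, which are not independent replicates, the log2 ratios at the 2 times had a Pearson r of 0.07 and a Spearman rho of 0.05. Simulated unchanged libraries gave means of 0.49 and 0.43, but their ratios spread by counting error only. The observed ratios held other differences between libraries too, with standard deviations across genes of 0.256 at 5 h and 0.583 at 24 h. A wider spread lowers r for the same covariance, so the observed and simulated correlations are not comparable. The covariance was 0.0108 against a simulated 0.00865, a difference of 0.00212. The single DMSO library cannot be split, so part of any excess may come from the shared control, and requiring at least 100 counts left 0 genes in the same direction at both times.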

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

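The correction for GC content and gene length and the floor in the size rule were added after the data had been seen, and the tests of hours in culture for the endoplasmic reticulum and hypoxia lists were chosen after the 5 h medians were known. The tests on GC content and on library depth were set out before their results were computed.

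Some genes and lists lay on opposite sides of DMSO at 5 h and 24 h of PBIT, which is why they are given here. The difference between the times was not tested, since there was 1 library per time. ATP6V0A4 was higher at 5 h (1.60) and lower at 24 h (-3.92), a log2 ratio of -5.52 between the PBIT libraries. B3GALT5, a galactosyltransferase gene, stood at 1.03 and -3.29, with -4.32 between them. GZMB stood at 1.15 and -2.15, with -3.30 between them. IL22 had 6 counts in DMSO, 39 at 5 h and 0 at 24 h, which against the floor of 3 counts per library is a log2 ratio of -3.47 between the PBIT libraries, at least 11.1-fold lower at 24 h. Against DMSO the same floor gives at least 1.84-fold lower, under the 2-fold limit. With the prior count 11 genes were past the size rule in opposite directions, these 4 among them, and with the floor 10 were, without IL22. Among lists, NF-kB targets (0.31 and -0.33) differed by -0.80 between the PBIT libraries, immediate early and activation genes (0.18 and -0.30) by -0.49, and proteasome subunits (-0.10 and 0.13) by 0.22. The proteasome list did not stand apart at either time once the GC and length trends were removed.

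The PBIT 24 h library differed from DMSO in 1068 genes by the size rule and the PBIT 5 h library in 156. After removal of the GC and length trends 1014 genes were past the rule at 24 h and 156 at 5 h. After thinning to the smallest library 1044 and 147 were. This argues against GC bias, length bias or depth as the whole cause of the larger number at 24 h. The genes were not all the same, however. With the trends removed, 279 of the 410 higher and 613 of the 658 lower genes at 24 h kept their call. The log2 ratio at 24 h had a Pearson r of 0.20 with GC content across genes. The DMSO library carries 5 h by its label and none of 24 h was among the samples, so the longer culture, an effect particular to 1 library and the longer exposure to PBIT cannot be told apart. A longer exposure to PBIT is therefore a candidate explanation that stays untested.

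The endoplasmic reticulum stress list was lower at 24 h, with a median of -1.13 and 19 of 21 members below 0. After removal of the GC and length trends the median was -1.20, which argues against those trends as its cause. At 5 h, with hours in culture matched, the list was at percentile 0.0, but that value rests on 1 PBIT library against 1 DMSO library and leaves hours open as the whole cause at 24 h. The difference between the PBIT libraries, a median of -0.74, cannot be told apart from an effect of hours in culture or of a single library. An effect of PBIT on the genes of this list stays open too, as untested.

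The hypoxia and glycolysis list was higher at 24 h, with a median of 0.66 and 32 of 33 members above 0. After removal of the GC and length trends the median was 0.55 and the list still stood apart, which argues against those trends as the cause. At 5 h, with hours matched, the list was within the limits, at percentile 73.7. The median of 0.73 between the PBIT libraries cannot be told apart from hours in culture, since cells kept longer could deplete oxygen or nutrients without any drug. A later effect of PBIT stays open too, as untested.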

How the results depend on the processing

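Halved counts, removal of the GC and length trends, matching on GC, and a floor of 3 counts for a count of 0 were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. DESeq2 size factors, total counts, a prior count of 0.5, thinning, leaving out mitochondrial genes, removal of the GC and length trends and the floor (657 lower genes at 24 h against 658) kept every count of genes within 1.5 times its main value. The genes behind a count could still change. With the GC and length trends removed, 279 of 410 higher and 613 of 658 lower genes at 24 h against DMSO kept their call. At 24 h against 5 h, 255 of 357 and 770 of 823 did.

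The other settings moved counts by more. Higher genes at 5 h against DMSO (117) numbered 238 without a filter, 19 with at least 100 counts, 354 at 1.5-fold, 7 at 4-fold, 19 with the whole interval beyond 2-fold and 70 with counts halved, and lower genes (39) numbered 108, 0, 98, 2, 2 and 18. At 24 h against DMSO, 1.5-fold gave 1533 higher and 1377 lower, 4-fold 12 and 148, the whole interval beyond 2-fold 205 and 299, and at least 100 counts 332 lower. At 24 h against 5 h, 1.5-fold gave 1470 higher and 1700 lower, 4-fold 10 and 211, the whole interval 192 and 422, and at least 100 counts 438 lower. Genes higher at both times (17) numbered 35 without a filter, 0 with at least 100 counts, 71 at 1.5-fold, 2 at 4-fold, 1 with the whole interval and 6 with counts halved, and genes lower at both times (15) numbered 41, 0, 40, 0, 0 and 3. Filters change the genes tested and stricter rules shrink the lists by construction. At 5 h this shows that most genes past the rule, the lower ones above all, rest on low counts.

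The number of lists that stood apart stayed between 9 and 11 at 5 h, 13 and 15 at 24 h, and 16 and 17 between the PBIT libraries. Of 711 list medians under alternatives, 691 kept their side of the limits, 10 moved inside, 10 moved outside and 0 changed direction while outside. For named genes, 1459 log2 ratios under other scaling or correction stayed within their counting error and 269 moved beyond it. Removal of the GC and length trends moved the log2 ratio by at most 0.36 at 24 h and 0.08 at 5 h, with sign changes for 12 and 11 of 288 genes. Scaling by total counts changed the sign of 1 and 12, and DESeq2 size factors of 1 and 0, and none of these genes was past the rule.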

Other observations

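Among regulators of cell-cycle entry and p53 targets, CDKN1A, the inhibitor p21, stood at 0.94 (0.82 to 1.06) at 5 h and -1.06 (-1.25 to -0.88) at 24 h, CDKN2D at -1.31 and CDKN1C at 1.06 at 24 h. The list of these inhibitors and G1 cyclins had medians of 0.01 and -0.01 at 5 h and 24 h, with 1 of 12 members higher and 2 lower by the size rule at 24 h. The p53 list had medians of 0.05 and 0.11, with 0 of 24 higher and 3 lower by the rule at 24 h, CDKN1A, TP53INP1 (-1.19) and ZMAT3 (-1.09). Replication-dependent histone genes, which poly(A) selection captures poorly, had medians of -0.12 and -0.66, with 5 of 13 lower at 24 h, such as H2BC21 (40 against 161 counts). Their percentiles of 2.98 at 5 h and 3.78 at 24 h lay within the limits, but 2.22 at 5 h with matching on GC and 1.47 at 24 h after removal of the GC and length trends lay outside. Apoptosis regulators had medians of 0.05 and 0.01 with none of 25 past the rule, and BIRC3 stood at 0.48 and -0.32. Genes of DNA damage repair had medians of -0.06 and 0.16, with RAD54L at 0.96 at 24 h. Their percentile at 24 h was 97.1, within the limits, and 99.94 after removal of the GC and length trends, outside them. Ribosomal protein genes had medians of -0.07 and -0.03 and none of 72 past the rule. None of these lists stood apart in the comparisons with DMSO at TMM scaling and expression matching.

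The chromatin, T cell and related lists had at most 2 members each past the size rule at 24 h, beside 7.38% of all tested genes. The lists are too small to tell such counts from that share. The H3K4 methyltransferase list had medians of -0.04 and 0.14, none of 15 past the rule, with MEN1 at 0.48 at 24 h. After removal of the GC and length trends its 24 h median was 0.04. The list of other histone demethylases had medians of 0.03 and -0.01, none of 17 past the rule, with KDM4B at 0.86 and KDM3A at 0.75 at 24 h. Germline and cancer testis genes had medians of 0.01 and -0.05, with 0 of 9 measured members higher and 2 lower at 24 h, PIWIL2 (18 against 60 counts) and BRDT (2 against 30 counts, -6.90 to -1.81). Core T-cell leukaemia transcription factors had medians of -0.01 and 0.16, with TCF12 at 0.66 and IKZF1 at 0.60 at 24 h and none of 16 past the rule. Their 24 h median was 0.05 after removal of the GC and length trends. Of 25 T cell identity genes (medians 0.00 and -0.15), the adaptor gene LAT was lower by the rule at 24 h at -1.23 (-1.27 to -1.20). Antigen presentation genes had medians of 0.00 and -0.14, with HLA-B (log2 interval -1.03 to -0.98) and HLA-DPB1 (-1.75) lower by the rule at 24 h. Cholesterol synthesis genes had medians of -0.07 and 0.00, with the sterol carrier gene STARD4 lower by the rule at 24 h at -1.27 (-1.32 to -1.22). None of these lists stood apart in the comparisons with DMSO under any alternative tried.

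The lists of B cell markers, of natural killer and cytotoxic markers, and of epithelial and fibroblast markers had at most 8 measured members each. B cell markers had medians of 0.09 and 0.45, with CD79B (110 against 58 counts) and IGLL1 (520 against 148) higher by the rule at 24 h. The epithelial and fibroblast list had a median of 0.22 at 24 h (percentile 77.8). At 5 h the lists of hypoxia and glycolysis (-0.01), fatty acid synthesis (-0.05), NOTCH1 targets (0.05), ATF4 (0.01), interferon (0.03), G1/S (-0.08), G2/M (-0.02), heat shock (-0.07) and metallothioneins (0.00) had medians within the limits. At 24 h the same held for MYC targets (0.03), nuclear genes of oxidative phosphorylation (0.09), mitochondrial genome genes (-0.15) and autophagy (-0.08). After removal of the GC and length trends the oxidative phosphorylation list was at percentile 97.71 at 24 h, outside the limits. Lists with under 5 measured members were given no percentile. Of myeloid markers, CD14 had 86, 65 and 13 counts in DMSO, PBIT 5 h and PBIT 24 h, CD68 had 472, 662 and 302, and FCER1G had 78, 78 and 31. Of erythroid and megakaryocyte markers, EPOR had 819, 786 and 932 counts, ITGA2B had 133, 222 and 94, and KLF1 had 5, 9 and 23.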
